A study of Saccharomyces cerevisiae BY4741 with 238 samples.

How the data were processed

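The data are one table of gene expression values for 238 libraries, each from 1 well of Saccharomyces cerevisiae strain BY4741. Per the labels' protocols, an overnight culture was spread by a robot over concentration grids of drug pairs in YPD and re-inoculated automatically, and wells whose growth was reduced to an intermediate level, with single-drug and drug-free wells, were lysed for RNA. Polyadenylated RNA was fragmented, reverse-transcribed from barcoded poly(T) primers that carry a 4-base unique molecular identifier (UMI), pooled and sequenced as 50 bp single-end reads, per the labels' protocols. Reads from such libraries lie near the 3' end of a transcript, so values are not divided by gene length. The submitters' processing notes name TopHat, UMI-tools and featureCounts and the genome build R64. Versions, the strand setting and the treatment of reads with several matches are not given in the sources used here. Near-identical copies and overlapping or antisense open reading frames therefore cannot be told apart, and values for PHO11 and PHO12, the CUP1 copies, paralogous ribosomal protein genes and the copies near the ribosomal DNA are uncertain.

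The values the authors deposited are a normalized signal, not whole counts. Every column has the same largest value (17026.2) and nearly the same total (595181 to 596851), and after multiplication by 239 77.2% of values were within 0.01 of a whole number and the others within 0.01 of the midpoint between whole numbers. This is the pattern of quantile normalization, in which each library receives the mean count at each rank, here over 239 libraries although 238 columns are present. The normalization is read from the values, since neither the labels nor the header names it. It gives all libraries the same distribution, so a change in the total amount of messenger RNA or a shift of most genes in one direction cannot be seen, and each change is relative to the other genes of the same library. A count model was planned before the data were examined, with limma on log2 values as the fallback for normalized values. The fallback was used, because the table holds no counts.

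Depth was estimated for each library from the ties that quantile normalization leaves: genes with the same number of reads share a value, and the value shared by genes with 30 reads gives the worth of 1 read. Estimated depth ranged from 64843 to 2017612 reads with a median of 568842, and 8 libraries lay below 142211, a share of 0.25 of the median. The limits on precision are set by these depths and by the spread between wells. The closest pair of libraries had a correlation of 0.9885 over log2 values (median over pairs 0.924, lowest 0.771), and 0 pairs were identical, so each library was counted as 1 replicate.

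Of 6717 features, 5015 with a mean value of at least 10 over all libraries were tested. Names and coordinates came from the RefSeq annotation of build R64, which matched 6025 features and left 692 unmatched. Values were transformed as log2(value + 1), so that fold changes are on this scale and understate the change of low genes. Groups were set from the drug concentrations and the relative growth rate in the labels. A single-drug culture with a relative growth of 0.35 to 0.66 was called growth-matched. All models were fitted with limma 3.58.1 (moderated tests with a mean-variance trend) in R 4.3.3. Comparisons of group means had terms for the experiment (the drug pair whose grid held the well) and for the growth-reference set. Slopes on growth inhibition, fitted within 1 experiment, had a term for the set alone. Curves on dose share and fits within a pair's own experiment had neither term. The growth-reference set is a batch label formed from the ratio of absolute to relative growth rate, which takes 2 values in an experiment (lower and higher). What this ratio stands for is not given in the labels. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 1.5-fold.

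5 kinds of comparison were made. Each growth-matched drug was compared with no drug. Each drug was also compared with the 3 other drugs, and each pair with its single drugs, where a gene was called only if all contrasts had the same sign, passed 1.5-fold, and the largest p passed after adjustment. For those comparisons the change nearest 0 is given. The slope on growth inhibition was fitted within the experiment that held a drug's concentration gradient and is given as the change at a relative growth of 0.5. The position of each combination culture between the mean profiles of its single drugs was computed over genes that differed between those drugs and correlated with its dose share, using 100000 two-sided permutations and adjustment over the 6 pairs. The dose share is the dose of the second drug over its median growth-matched dose in the same experiment, divided by the sum of that quantity for both drugs. Departure from interpolation, fitted as a curve of each gene on dose share with the single-drug cultures of the same experiment included, was set as an alternative beforehand. A curve fitted to the combination cultures alone was added after the data were seen. Its value at a share of 0.5 is set against a straight line drawn to shares of 0 and 1, beyond the cultures measured.

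Of 40 gene lists, written before the data were examined, the 36 with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists in a comparison. For drugs against other drugs and for pairs the list contrast was against the mean of the other drugs or of both single drugs. Counts of called members are given over all genes tested and, where they differ, "adjusted over the list alone". Genes named in the text follow a rule fixed beforehand: among called genes with a mean log2 value of at least 4, the 5 with the largest rise and the 5 with the largest fall, the 2 called members with the smallest p in each of the 4 lists with the smallest camera p, and the members of a list of drug targets and transporters. The rule and the list tests were written for log2 scaled counts and were applied to log2 values. Other genes named were chosen after their values were seen, and the text says so.

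The fits were tested on simulated data made from the real means and spreads with 200 changed genes. The changes were 0.75, 1, 1.5 and 2 on the log2 scale, and groups did not differ otherwise. With fewer changed genes the adjustment over genes is stricter, so recovery in real comparisons can be lower. Changes of 1 on the log2 scale were recovered against no drug in 88% (cycloheximide), 94% (LiCl), 88% (myriocin) and 88% (rapamycin) of 50 such genes. The alternatives left out the filter, the fold minimum or shallow libraries, changed the pseudocount, the growth window, the batch term or the weight of libraries, added growth as a covariate, or left out single libraries in turn. Permutations and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.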

Results

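Transcript levels were measured in 238 cultures of budding yeast strain BY4741 during exposure to 4 growth inhibitors alone or in pairs. BY4741 is a laboratory MATa strain with marker mutations at HIS3, LEU2, MET17 and URA3. Cycloheximide blocks translation elongation, LiCl is a toxic salt that inhibits lithium-sensitive phosphatases, myriocin inhibits serine palmitoyltransferase of sphingolipid synthesis, and rapamycin inhibits TOR complex 1. The cultures fell into 11 with no drug (relative growth 1.02 ± 0.0371, SD) and 4 growth-matched single-drug groups: cycloheximide (n = 10, 0.533 ± 0.0520), LiCl (n = 10, 0.553 ± 0.0510), myriocin (n = 11, 0.541 ± 0.0841) and rapamycin (n = 11, 0.506 ± 0.0793). A further 13, 18, 14 and 19 cultures held these drugs at other growth rates. The pairs had 22 cultures (cycloheximide with LiCl), 20 (cycloheximide with myriocin), 19 (cycloheximide with rapamycin), 26 (LiCl with myriocin), 18 (LiCl with rapamycin) and 16 (myriocin with rapamycin). Estimated depth was 64843 to 2017612 reads per library, with group medians from 282381 (cycloheximide with myriocin) to 909526 (cycloheximide with LiCl). Values are quantile-normalised counts. Errors are SE after a log2 change and SD after a mean, and p-values come from limma with Benjamini-Hochberg adjustment over 5015 genes. In comparisons of groups they measure the spread between wells that differ in dose, and for pairs in dose share. The wells may share an inoculum.

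The strain's markers were read first. LEU2, MET17 and URA3 were at the lowest value in all 238 libraries (mean 0.08), while HIS3 had a mean of 16.6 ± 8.03, from reads whose origin within the locus is not given. All 8 mitochondria-encoded transcripts on the list, COX1 among them, were also at the lowest value in 238 libraries. Among markers of the other mating type, MF(ALPHA)2 had the highest mean (9.78), and among meiosis genes NDT80 had the highest (20.5 ± 8.76).

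What each drug changed at a comparable growth rate was asked against the drug-free cultures. Under cycloheximide 73 genes rose and 51 fell. SNZ1, of vitamin B6 synthesis, rose by 1.68 ± 0.218 log2 (85.5 ± 26.9, n = 10, against 25.6 ± 6.74, n = 11; adjusted p = 3.71e-07), and DRS1, a helicase of ribosome assembly, by 1.34 ± 0.225 (p = 7.6e-05). The metallothionein genes CUP1-1 and CUP1-2 and the open reading frames YHR052W-A and YHR054W-A beside them rose by 1.26 to 1.33, as copies whose reads are not separable. HXT1, a low-affinity glucose transporter, rose by 1.28 ± 0.320 (p = 0.00981). STR3, an enzyme of methionine synthesis, fell by 1.34 ± 0.287, the copper transporter CTR1 by 1.05 ± 0.327, and SNX41, FMP23 and YIL100C-A fell by 1.09, 1.08 and 1.27.

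Among fixed lists under cycloheximide, 6 of 26 heat shock genes rose, including the Hsp90 co-chaperone AHA1 (0.67 ± 0.113) and the Hsp70 gene SSA3 (0.94 ± 0.164), with a list median of 0.34 (camera adjusted p = 1.47e-11; adjusted p = 0.0767 with an estimated correlation). Of 38 general stress genes 7 rose (8 adjusted over the list alone), among them HSP12 (1.04 ± 0.198) and SPI1 (0.62 ± 0.114; adjusted p = 0.241 with an estimated correlation). Of 63 ribosome biogenesis genes 5 rose (6 adjusted over the list alone), among them PWP1 (0.82 ± 0.216; adjusted p = 0.174 with an estimated correlation). Of 67 mitochondrial ribosomal protein genes RSM19 and MRPL49 fell (-0.59 ± 0.158 and -0.61 ± 0.188), and the list median was -0.31 (camera adjusted p = 2.57e-10; adjusted p = 0.0767 with an estimated correlation). The ammonium permease gene MEP2 rose by 1.20 ± 0.362 (p = 0.0388) from 5.17 to 15.2, and the amino acid permease gene GAP1 was not called (0.85 ± 0.287, p = 0.072). RPL28, which encodes the protein at the drug's binding site, was not called (0.03 ± 0.0630). Of the 18 named calls, 17 had the same sign in each of 3 experiments, and all 18 in both growth-reference sets. Here and for the other drugs the same libraries selected the genes, so agreement in sign was likely and is not replication. With only the drug-free cultures below an OD600 of 0.9, 73 genes were called (56 higher and 17 lower), 58 of them shared, and with libraries weighted by quality 246 were called.

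LiCl changed 428 genes (221 higher, 207 lower). The methionine synthase gene MET6 (V:339864-342167) fell by 2.23 ± 0.220 (p = 6.13e-11, n = 10 against 11) and the S-adenosylmethionine synthetase gene SAM1 by 1.37 ± 0.162. In all 18 of 24 sulfur and methionine genes fell, with 0 rising (median -0.93, camera adjusted p = 5.29e-17; adjusted p = 0.0067 with an estimated correlation). Phosphate starvation genes fell too: 10 of 14 were lower, among them SPL2, a regulator of phosphate uptake (-2.63 ± 0.247, p = 2.18e-11), and the acid phosphatase gene PHO5 (II:429548-430951; -2.26 ± 0.227, mean 51.6 against 174), with a list median of -0.79 (adjusted p = 0.0067 with an estimated correlation). Osmotic stress genes rose, 9 of 20 (10 adjusted over the list alone), among them ALD3, an aldehyde dehydrogenase (2.01 ± 0.199; 643 ± 460 against 163 ± 113), and the catalase gene CTT1 (1.43 ± 0.180), with a median of 0.60 (adjusted p = 0.0067 with an estimated correlation).

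HXT1 had the largest rise under LiCl among genes in the naming rule (2.49 ± 0.307; 104 ± 98.7 against 12.9 ± 5.80), followed by YBR116C and its neighbour TKL2, a transketolase gene (2.28 ± 0.383 and 2.16 ± 0.373), and YOL150C (1.79 ± 0.326). Low-affinity glucose transport genes rose in 2 of 5 cases (adjusted p = 0.0197 with an estimated correlation), and 5 of 16 G2/M genes rose (adjusted p = 0.0197 with an estimated correlation). Of 63 ribosome biogenesis genes 18 rose (22 adjusted over the list alone), of 47 amino acid biosynthesis genes 6 fell, and of 37 oxidative phosphorylation genes 5 fell (6 adjusted over the list alone). These 3 lists were past the threshold with the preset correlation and not with the estimated one (adjusted p = 0.206, 0.262 and 0.228 with an estimated correlation). ENA1, a sodium and lithium pump gene, was not called (0.17 ± 0.209, p = 0.642), nor was MET22, a lithium-sensitive phosphatase gene (-0.29 ± 0.195, p = 0.321). All 12 named calls had the same sign in each of 3 experiments. The count was 244 with a pseudocount of 10.

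Myriocin changed 362 genes. Genes of ribosome assembly rose: 28 of 63 ribosome biogenesis genes were higher (35 adjusted over the list alone), among them CGR1 (1.60 ± 0.320), PWP2 (1.46 ± 0.356), RLP24 (1.39 ± 0.224; 39.4 ± 8.27, n = 11, against 20.1 ± 10.5) and UTP7 (1.11 ± 0.217). The list median was 0.65 (camera adjusted p = 4.61e-16; adjusted p = 0.176 with an estimated correlation). Cytosolic ribosomal protein genes had a median of 0.19, with 2 of 138 called, RPL22B (0.90 ± 0.196) and RPS9A (1.01 ± 0.251; adjusted p = 0.276 with an estimated correlation). GRE2, a methylglyoxal reductase gene, rose by 1.43 ± 0.318, with YOL150C beside it at 1.39 ± 0.337.

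Phosphate starvation genes fell under myriocin in 10 of 14 cases (median -0.75, adjusted p = 0.0125 with an estimated correlation), led by SPL2 (-2.13 ± 0.256, 25.7 ± 6.27 against 140 ± 49.6, p = 8.3e-08), PHO12 (-1.87 ± 0.247) and PHO5 (-1.85 ± 0.235). The full gradient did not show this fall: its median was -0.01, and 0.19 with 0 of 14 called lower by limma when drug-free libraries were left out. In its 17 cultures with a relative growth of at least 0.35 the median was -0.33. Without drug-free libraries it was -0.13 there, with 1 of 14 called lower. Of 16 daughter-specific and cell separation genes 5 fell, among them the chitinase gene CTS1 (-0.68 ± 0.0920, p = 5.98e-07) and EGT2 (-0.77 ± 0.223), with a median of -0.52 (adjusted p = 0.0125 with an estimated correlation). The amino acid permease gene DIP5 fell by 1.61 ± 0.312. The genes of the inhibited enzyme, LCB1 and LCB2, were not called (0.29 ± 0.124, p = 0.105, and 0.27 ± 0.145, p = 0.213), and the drug pump gene PDR5 had an adjusted p of 0.0128 at a change of 0.56 ± 0.160, under the fold minimum. Of 15 named calls 14 had the same sign in each of 3 experiments. With the library-number series as the batch term 240 genes were called, and 202 with a pseudocount of 10.

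Rapamycin changed 268 genes (147 higher, 121 lower). Genes for nitrogen sources rose: GAP1 (XI:515063-516871) by 1.88 ± 0.274 (108 ± 59.2, n = 11, against 19.4 ± 6.29; p = 1.19e-06) and MEP2 by 2.68 ± 0.345 (p = 9.4e-08). Of 21 nitrogen catabolite repression genes 8 rose and 2 fell (camera adjusted p = 0.000346; adjusted p = 0.196 with an estimated correlation). Heat shock genes rose in 11 of 26 cases, among them AHA1 (0.89 ± 0.108, p = 2.86e-08) and STI1 (0.84 ± 0.113), both Hsp90 co-chaperones, with a median of 0.48 (adjusted p = 0.012 with an estimated correlation). SER3, of serine synthesis (V:322686-324095), rose by 1.90 ± 0.217 (232 ± 40.8 against 55.9 ± 11.9), FIT3, of iron uptake, by 1.94 ± 0.264, SPG4 by 1.92 ± 0.337 and YJL133C-A by 2.18 ± 0.265. The general stress genes DDR2 and SSA4 rose by 1.12 ± 0.186 and 0.99 ± 0.184.

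Lower under rapamycin were 7 of 14 phosphate starvation genes (median -0.61, adjusted p = 0.0271 with an estimated correlation), among them SPL2 (-1.66 ± 0.246), PHO5 (-1.62 ± 0.226) and VTC3, of polyphosphate synthesis (-0.84 ± 0.105). RCN1, a calcineurin regulator, fell by 1.65 ± 0.208, ARO9, an aromatic aminotransferase gene, by 1.60 ± 0.208 and YOR385W by 1.49 ± 0.257. Retrograde response genes rose in 3 of 8 cases (adjusted p = 0.0271 with an estimated correlation). Cytosolic ribosomal protein genes had a median of -0.19 (camera adjusted p = 6.57e-21; adjusted p = 0.231 with an estimated correlation), of which RPS26B alone of 138 was called (-0.59 ± 0.0930). TOR1 and FPR1, which encode targets of the drug, were not called (-0.50 ± 0.228, p = 0.151, and 0.12 ± 0.0800, p = 0.366). All 17 named calls had the same sign in each of 3 experiments, and a pseudocount of 10 gave 173 calls.

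**Figure D1:**
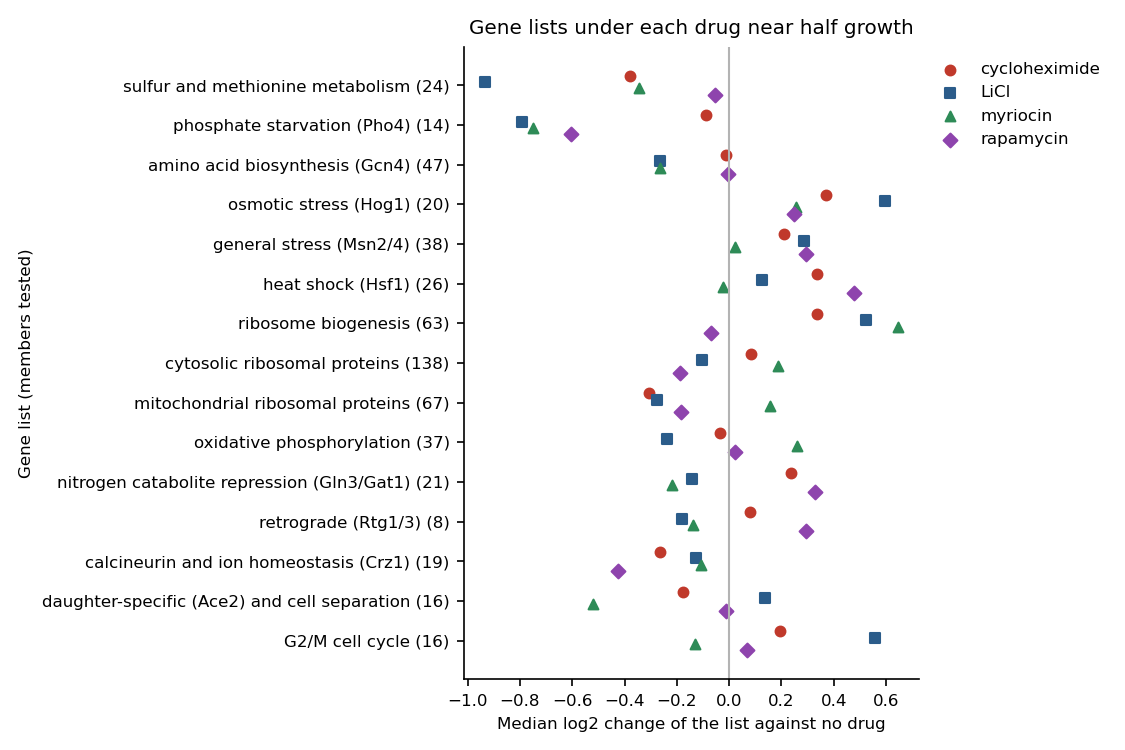
Median log2 change against no drug (x axis) of 15 gene lists (y axis, members tested in brackets) under each drug, 1 marker per drug. The LiCl median lies furthest to the left for sulfur and methionine genes (-0.93), and LiCl, myriocin and rapamycin lie between -0.79 and -0.61 for phosphate starvation genes. The full myriocin gradient did not show this fall (median -0.01, and -0.33 in cultures with a relative growth of at least 0.35).

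Across all 4 drugs, 5 genes were higher (RRT1, YRO2, NQM1, GND2 and YHR033W) and 4 lower (YLR154C-H, YLR156C-A, YLR157C-C and YLR159C-A, near-identical copies beside the ribosomal DNA). NQM1, a transaldolase gene, rose by 1.24, 1.78, 1.31 and 1.24 under cycloheximide, LiCl, myriocin and rapamycin. These genes were named after their values were seen. Independent lists would share 0.00333 higher and 0.00187 lower genes. Unchanged groups simulated against the shared controls shared at most 0 in 20 draws, but no drug had an effect there, so that outcome was nearly fixed. With the controls split so that each drug had its own few, 0 genes were common to all in any of 20 draws. That can come from the loss of controls, so neither check settles sharing through common controls.

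Which genes set 1 drug apart from the 3 others at comparable growth was tested next. LiCl had 36 such genes (11 higher, 25 lower). MET6 was lower than under every other drug by at least 1.35 ± 0.343 (p = 0.0162), SAM1 by 0.77 ± 0.218, the pyrimidine synthesis gene URA1 by 1.00 ± 0.228 (42.6 ± 17.8 against 101 ± 24.0 under cycloheximide and 150 ± 21.1 under myriocin) and BNA7, of kynurenine metabolism, by 1.14 ± 0.193. Of 37 oxidative phosphorylation genes 4 were lower (5 adjusted over the list alone), among them the cytochrome oxidase genes COX9 and COX6 (-0.64 ± 0.128 and -0.64 ± 0.130; list median -0.34, adjusted p = 0.0984 with an estimated correlation). Higher were FCP1, a phosphatase of RNA polymerase II (0.99 ± 0.163, p = 0.000865), COG4, of Golgi transport (0.88 ± 0.142), VHS3 (0.73 ± 0.201) and YMR317W (1.02 ± 0.241). The count fell to 20 without cycloheximide replicate 3 and to 22 without LiCl replicate 1 or 2. Without shallow libraries 39 genes were called (19 higher, 20 lower), 17 of them shared, and with the library-number series 52, of which 18 were shared.

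Myriocin had 12 genes apart (6 higher, 6 lower) and rapamycin 20 (15 higher, 5 lower). Under myriocin the peptide transporter gene PTR2 (-1.34 ± 0.272, p = 0.00555), LEU4, of leucine synthesis (-0.97 ± 0.166; 115 ± 19.2 against 312 ± 79.3 under cycloheximide and 264 under LiCl), the permease gene AGP1 (-0.80 ± 0.190), the glucose transporter gene HXT3 (-0.81 ± 0.190) and the polo kinase gene CDC5 (-0.75 ± 0.190) were lower, while TOS2 (1.01 ± 0.249), EEB1 (0.88 ± 0.222) and NOP16, of ribosome assembly (0.88 ± 0.171), were higher. Its 67 mitochondrial ribosomal protein genes had a median of 0.35 and its 16 daughter-specific genes of -0.50, with 0 members called in either list (limma; 1 lower daughter-specific gene adjusted over the list alone) and an adjusted p = 0.0264 with an estimated correlation for both. Under rapamycin the citrate synthase gene CIT2 of the retrograde response (1.53 ± 0.319, p = 0.0249; 153 ± 70.6 against 38.8 ± 21.9 and 43.8 ± 14.2 under cycloheximide and LiCl), SER3 (1.43 ± 0.352), the glutamate dehydrogenase gene GDH3 (1.27 ± 0.313), OPI3, of phospholipid synthesis (1.22 ± 0.303), SPG4 (1.72 ± 0.444) and MET10, of sulfite reduction (1.04 ± 0.266), were higher. Lower were BDH2 (-1.17 ± 0.309), TOS3 (-1.10 ± 0.288), and the snoRNA-binding protein gene NOP58 (-0.68 ± 0.147) with YOR309C beside it. Its 63 ribosome biogenesis genes had a median of -0.55 with 1 called lower (7 adjusted over the list alone; adjusted p = 0.09 with an estimated correlation). For cycloheximide limma called 0 genes, with 127 at an unadjusted p under 0.05, against a recovery of 62% for simulated changes of 1, and its 14 phosphate starvation genes had a median of 0.47 against the mean of the other drugs (5 higher adjusted over the list alone; adjusted p = 0.0371 with an estimated correlation).

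These last counts rested on few libraries. The myriocin count of 12 became 58 without myriocin replicate 1 or cycloheximide replicate 1, 1 without LiCl replicate 1, LiCl replicate 2 or rapamycin replicate 10, 2 without LiCl replicate 4, 3 without cycloheximide replicate 3 and 6 without rapamycin replicate 11. The rapamycin count of 20 became 0 and 2 without rapamycin replicates 10 and 11, 10 and 7 without rapamycin replicates 6 and 7, 8 without myriocin or cycloheximide replicate 1, 9 without myriocin replicate 10, 7 and 11 without cycloheximide replicates 2 and 5, and 13 without LiCl replicate 8. For cycloheximide 1 gene was called without myriocin, cycloheximide or LiCl replicate 1.

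How expression followed growth inhibition was read from the concentration gradients, which spanned relative growth of 0.465 to 1.12 for cycloheximide (22 cultures), 0.511 to 1.04 for LiCl (26), 0.0358 to 1 for myriocin (22) and 0.356 to 1.03 for rapamycin (25). At a relative growth of 0.5 the fitted line for LiCl gave a change of -2.32 ± 0.183 for PHO5, -1.51 ± 0.240 for MET6, 2.33 ± 0.228 for ALD3 and -1.08 ± 0.184 for ARG4, an arginine synthesis gene. For rapamycin it gave 2.36 ± 0.171 for GAP1, 2.91 ± 0.222 for MEP2 and 2.51 ± 0.103 for FIT3. For cycloheximide SNZ1 rose by 2.07 ± 0.121, MEP2 by 1.95 ± 0.316 and GAP1 by 1.30 ± 0.265, and for myriocin RLP24 rose by 1.58 ± 0.182 and AGP1 fell by 0.97 ± 0.0940. Genes with such a trend numbered 267 for cycloheximide (129 higher, 138 lower), 338 for LiCl (133 higher, 205 lower), 803 for myriocin (400 higher, 403 lower) and 303 for rapamycin (170 higher, 133 lower). With libraries weighted by quality the LiCl trend had 245 higher and 243 lower.

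Along the LiCl gradient 21 of 47 amino acid biosynthesis genes fell (23 adjusted over the list alone; median -0.59, adjusted p = 0.0485 with an estimated correlation) and 14 of 38 general stress genes rose (15 adjusted over the list alone; adjusted p = 0.0485 with an estimated correlation). Along the rapamycin gradient 10 of 21 nitrogen catabolite repression genes rose and 1 fell (adjusted p = 0.00544 with an estimated correlation), and 7 of 67 mitochondrial ribosomal protein genes fell (adjusted p = 0.086 with an estimated correlation). Along the cycloheximide gradient 8 of 21 nitrogen catabolite repression genes rose (median 0.48, adjusted p = 0.0518 with an estimated correlation). Along the myriocin gradient 52 of 63 ribosome biogenesis genes rose (median 0.98, adjusted p = 0.125 with an estimated correlation) and 9 of 16 glucose-repressed genes fell (adjusted p = 0.245 with an estimated correlation). In the 17 of its 22 cultures with a relative growth of at least 0.35, 15 of 63 ribosome biogenesis genes rose (median 0.57), 4 of 16 glucose-repressed genes fell, and 393 genes in all had a trend. The cycloheximide count was 170 (103 higher, 67 lower) in cultures below an OD600 of 0.9, the rapamycin count 481 with no filter on low values, and pseudocounts of 10 gave 129, 389 and 153 for cycloheximide, myriocin and rapamycin.

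Whether the profile of a pair moved from the profile of one drug to that of the other with the dose share was tested within each pair, over 141 to 681 genes that differed between the single drugs. Position followed dose share in all 6 pairs: Pearson's r was 0.986 for cycloheximide with LiCl (Spearman's rho 0.990), 0.932 for cycloheximide with myriocin (0.964), 0.951 for cycloheximide with rapamycin (0.946), 0.939 for LiCl with myriocin (0.921), 0.966 for LiCl with rapamycin (0.969) and 0.980 for myriocin with rapamycin (0.962). Each permutation p, raw and adjusted over 6 pairs, was 1e-05, the smallest that the permutations allow. Without the 2 cultures farthest from the median share r was 0.924 to 0.989. Each pair lay in 1 experiment and its combinations in 1 growth-reference set, so the correlations are within-batch values. The single-drug mean profiles at the ends come from 3 experiments and both sets, without batch adjustment. Positions, and their offsets from the dose share, can therefore carry batch differences. In cycloheximide with rapamycin 15 of 19 cultures lay nearer the cycloheximide profile than their dose share (median position 0.174 at a median share of 0.468). In LiCl with rapamycin 2 of 18 and in myriocin with rapamycin 4 of 16 lay below their share (median positions 0.696 and 0.684 at shares of 0.436 and 0.516). These offsets were noted after the values were seen, a dose share is scaled to single-drug doses, and the offsets depended on the genes used. Over all tested genes the counts below the share were 16, 2 and 0 in these pairs, but went from 13 to 22 of 22 in cycloheximide with LiCl (20 without shallow libraries), from 16 to 4 of 26 in LiCl with myriocin and from 6 to 10 of 20 in cycloheximide with myriocin.

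**Figure D2:**
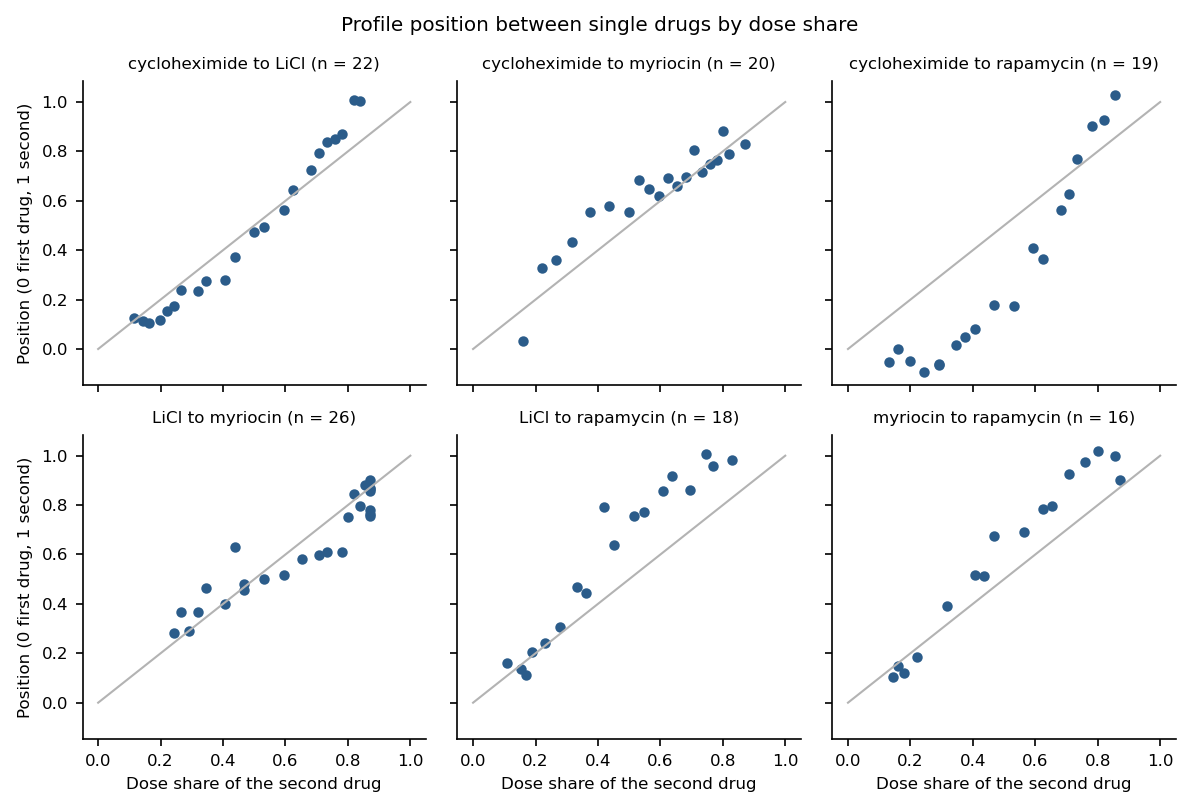
Position of each combination culture between the mean profiles of the first (0) and second drug (1), against its dose share, with 1 panel per pair, 1 point per culture and a grey line where both are equal. In cycloheximide with rapamycin 15 of 19 points lie below the line, and in LiCl with rapamycin 2 of 18 do.

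Genes beyond both single drugs were sought by comparing each pair with its 2 single drugs. LiCl with myriocin had 13 (7 higher, 6 lower). GRE1, a hydrophilin gene of the osmotic response (XVI:128632-129138), was higher than under either drug by at least 2.50 ± 0.384 (p = 9.07e-05). Within the pair's experiment its mean was 120 ± 98.2 (n = 26) against 8.52 ± 0.808 under LiCl (n = 2) and 14.3 ± 6.94 under myriocin (n = 7). GND2, of the pentose phosphate pathway, was higher by 1.18 ± 0.290 (230 ± 95.1 against 113 ± 6.97 and 84 ± 16.9 in the same cultures), AGX1, of glycine synthesis, by 1.12 ± 0.225, the lactate dehydrogenase gene CYB2 by 1.09 ± 0.218 (p = 0.00137), and OLE1, the fatty acid desaturase gene (VII:398628-400160), by 0.81 ± 0.162. Lower were ARG4 (-1.20 ± 0.242; within the experiment 13.5 ± 7.91 against 20.9 ± 3.05 and 31.6 ± 6.80), HIS4, of histidine synthesis (-0.72 ± 0.124), the glutamine synthetase gene GLN1 (-0.74 ± 0.173), GDH1, of glutamate synthesis (-0.63 ± 0.134), and WTM1 (-0.66 ± 0.106).

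The 20 osmotic stress genes had a median of 0.62 in LiCl with myriocin against the mean of both drugs, with 1 called higher (3 adjusted over the list alone; camera adjusted p = 3.5e-16, adjusted p = 0.0201 with an estimated correlation). Of 47 amino acid biosynthesis genes 2 were lower (adjusted p = 0.388 with an estimated correlation). Over cultures with a dose share of 0.25 to 0.75 62 genes were called, 13 of them shared. With libraries of the pair's own experiment alone, which holds 2 LiCl cultures at this growth, 2 were called.

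**Figure D3:**
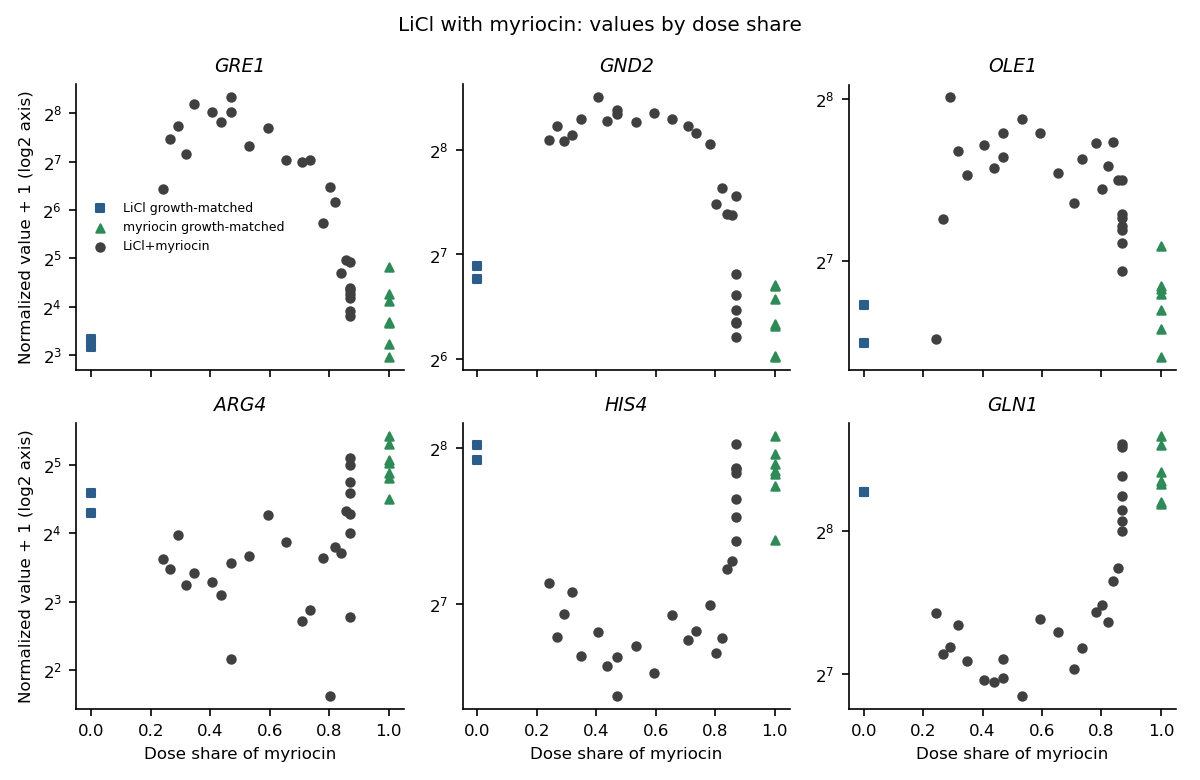
Normalised value + 1 (log2 axis) of 6 genes against the dose share of myriocin in the LiCl with myriocin experiment, with 1 point per culture: combinations (n = 26), LiCl at share 0 and myriocin at share 1. GRE1, GND2 and OLE1 lie higher at intermediate shares than in most single-drug cultures, and ARG4, HIS4 and GLN1 lie lower.

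Cycloheximide with myriocin had 10 genes higher than under both drugs and 0 lower, among them ACS2, of acetyl-CoA synthesis (1.90 ± 0.343, p = 0.000326), GPI13, of membrane anchor synthesis (1.88 ± 0.319), PUS1 (1.65 ± 0.340), CAF40 (1.46 ± 0.281) and UFD2 (1.13 ± 0.243). The group means show rises of this size in none of the 5 (GPI13 20.0 ± 6.32, n = 20, against 32.9 ± 9.90 under cycloheximide and 17.9 ± 6.17 under myriocin). The fit adjusts for experiment and growth-reference set, and this experiment holds 2 single-drug libraries, both in the other set than its combinations. Without myriocin replicate 1, 4 genes were called and 1 of the 10 was kept, and without cycloheximide replicate 1, 100 were called and 6 kept. In the other pairs limma called 0 genes, with 90 (cycloheximide with LiCl), 207 (cycloheximide with rapamycin), 173 (LiCl with rapamycin) and 27 (myriocin with rapamycin) at an unadjusted p under 0.05, and recovered 66%, 76%, 88% and 78% of simulated changes of 1. Against the mean of both drugs, 16 G2/M genes had a median of 0.32 in cycloheximide with LiCl (adjusted p = 0.0345 with an estimated correlation). Without cycloheximide replicate 2, 3 genes were called for cycloheximide with LiCl, and 1 gene each for cycloheximide with rapamycin without cycloheximide replicate 5 and for LiCl with rapamycin without LiCl replicate 8.

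Departure of a pair from the interpolation between its single drugs is a broader measure, since a gene can depart without passing both drugs. Its fit has no term for the growth-reference set. Combinations all lie in the higher set, while the single-drug ends hold lower-set wells, so a difference between sets can enter it. LiCl with myriocin had 277 departing genes, and 106 of them were also called in the curve over the combination cultures alone. In every pair the combination cultures are in both fits, so calls in both curves overlap in part by construction and are not independent evidence. Of 20 osmotic stress genes 14 rose (median 1.01, camera adjusted p = 9.65e-31, adjusted p = 0.00175 with an estimated correlation), among them GRE1 (4.20 ± 0.319), the glycerol importer gene STL1 (3.26 ± 0.551), SIP18 (2.63 ± 0.280) and DAK1, of dihydroxyacetone detoxification (1.29 ± 0.116). Of 63 ribosome biogenesis genes 19 rose (23 adjusted over the list alone; adjusted p = 0.148 with an estimated correlation) and of 24 sulfur and methionine genes 7 fell (8 adjusted over the list alone; adjusted p = 0.102 with an estimated correlation), MET6 by 1.80 ± 0.244. Cycloheximide with rapamycin had 202 (144 higher, 58 lower), 35 of them in both curves. There 35 of 63 ribosome biogenesis genes rose (37 adjusted over the list alone; median 0.66, adjusted p = 0.0548 with an estimated correlation) and 4 of 138 cytosolic ribosomal protein genes (median 0.22, adjusted p = 0.0497 with an estimated correlation). NOP14, of ribosome assembly (0.89 ± 0.155), and LEU1 and BAT1, of leucine synthesis (0.73 ± 0.135 and 0.77 ± 0.100), were called in both. The genes of this and the next paragraph were chosen after their values were seen, from members of the fixed lists called in both curves.

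In cycloheximide with LiCl 60 genes departed (37 higher, 23 lower; 21 in both curves). PHO5 and SPL2 were higher than the interpolation by 1.18 ± 0.186 and 1.14 ± 0.146, and 5 of 14 phosphate starvation genes rose (adjusted p = 0.0588 with an estimated correlation). HSP12 was higher by 0.88 ± 0.135, and 3 of 16 G2/M genes rose (adjusted p = 0.00853 with an estimated correlation). In myriocin with rapamycin 67 genes departed (47 higher, 20 lower; 26 in both), with 6 of 26 heat shock genes higher (median 0.39, adjusted p = 0.0634 with an estimated correlation), among them SSA4 (p = 2.2e-06) and SSA3 (1.12 ± 0.203), and MEP2 higher by 1.27 ± 0.292. In LiCl with rapamycin 16 departed (13 higher, 3 lower; 4 in both), among them SER3 (1.00 ± 0.199) and GDH3 (1.06 ± 0.205). In cycloheximide with myriocin 55 were called (47 higher, 8 lower; 3 in both), but each end of that interpolation is 1 library, in the other growth-reference set than the combinations, so departure cannot be told from a difference of those libraries and no list is given. Both ends in cycloheximide with LiCl, the LiCl end in LiCl with myriocin and the rapamycin end in cycloheximide with rapamycin hold 2 libraries. Over 648 list tests against no drug, other drugs or single drugs and along gradients, 255 results passed with the preset correlation (128 higher, 127 lower) and 25 with the estimated one.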

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

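The test of the cycloheximide with myriocin genes, the tests of the phosphate genes without drug-free libraries and the counts over other splits for comparisons of group means were chosen after their results were seen. The other tests in this part, on the osmotic genes, on culture density and over splits for trends and curves, were set down before.

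Phosphate starvation genes were lower under LiCl, myriocin and rapamycin than without drug, with 10, 10 and 7 of 14 called. High density of the drug-free wells could raise them there, but with only the 8 drug-free cultures below an OD600 of 0.9 the list medians were -0.82, -0.79 and -0.69, none nearer 0 than with all drug-free cultures (highest median -0.69). Values peculiar to the drug-free libraries are argued against for LiCl and rapamycin, since the gradients fitted without those libraries still gave medians of -0.62 and -0.59 (highest -0.586). For myriocin the same fit gave 0.192, and -0.131 in cultures with a relative growth of at least 0.35 (-0.327 with drug-free libraries), both on the side that such a cause predicts. In a fit without drug-free libraries the genes were lower under myriocin than under cycloheximide (median -0.404, upper quartile -0.331, 13 of 14 below 0). That contrast does not decide, since higher values under cycloheximide would give it too. The cycloheximide gradient without drug-free libraries had a median of -0.046, so it showed no such rise. The cause therefore cannot be told apart for myriocin. The gradient test was first set down for the 3 drugs together and was divided after the result was seen, the contrast with cycloheximide was added after it, and a direct action of the drugs on phosphate signalling was not tested.

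Osmotic stress genes stood above the mean of both single drugs in LiCl with myriocin (median 0.62), with 1 of 20 above each drug. An offset between mixed and single-drug cultures is argued against by the combination cultures alone, where the median curvature of the list with dose share was 1.592 (quartiles 0.762 and 2.255), with 19 of 20 members above 0. In the same cultures the median was 1.507 with relative growth and 1.603 with estimated depth as a covariate. These values argue against growth or depth differences among the mixed cultures as sole causes of the curvature. That fit holds no single-drug culture, so it cannot test slower growth or other depth of mixed than of single-drug cultures. Mean relative growth was 0.471 in the mixed cultures, 0.553 under LiCl and 0.541 under myriocin. Doses differed too: mixed cultures reached 0.9617 µg/ml myriocin and 17853 µg/ml LiCl, against at most 0.510 and 15726 in growth-matched single-drug cultures. Total dose was not held equal across dose shares, so curvature with share cannot be told apart from a response to dose. A response of the cells to the joint exposure is a candidate explanation, found and examined on the same wells of 1 experiment. The curve reaches past the measured shares (0.242 to 0.87), and its size depends on that extrapolation.

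The 10 genes above both drugs in cycloheximide with myriocin may come from the 2 single-drug libraries of that experiment: without myriocin replicate 1, 1 of the 10 calls was left. Low depth is open: with a pseudocount of 10, 2 calls were left, yet the genes' median value (35.9) was close to that of tested genes (37.7) and 5 of the 10 lay under it. That depth test was tightened after these values were seen, and as first worded it would have counted towards low depth. The estimated depth of myriocin replicate 1 was 172720 reads against a median of 300643 in the experiment. A biological response of these genes cannot be told apart from the state of those 2 libraries, since the combinations and single drugs of this experiment also lie in different growth-reference sets.

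Chance assignment of cultures was examined with 100 splits per comparison, the real one included. It is excluded for cycloheximide, LiCl, myriocin and rapamycin against no drug, where 1 split, the real one, gave as many genes as observed (124, 428, 362 and 268 against at most 8, 76, 2 and 135 in other splits). It is excluded too for the trends of cycloheximide, LiCl, myriocin and rapamycin (267, 338, 803 and 303 against at most 23, 0, 266 and 104). For LiCl, myriocin and rapamycin against the 3 other drugs the counts were 36, 12 and 20 against at most 3, 0 and 1. Those splits mixed wells of drugs that differ in many genes, which widens the spread within groups. Few calls in them were likely beforehand, so chance is not excluded for genes apart from the other drugs. The pairs cycloheximide with myriocin and LiCl with myriocin had 10 and 13 against 0 and 0, in splits that mixed groups in the same way. Splits of group means moved cultures across experiments and growth-reference sets, while each pair's combinations lie in 1 of each. For the pairs they therefore cannot exclude a batch difference, such as that of the 2 single-drug libraries in cycloheximide with myriocin. With 0 genes called, all 100 splits were as large for cycloheximide against the other drugs (highest other 8) and for cycloheximide with LiCl, cycloheximide with rapamycin, LiCl with rapamycin and myriocin with rapamycin (highest other 0, 0, 1 and 0). For the curves over combination cultures 1 split was as large for cycloheximide with LiCl, cycloheximide with rapamycin and myriocin with rapamycin (109, 114 and 75 against at most 0, 1 and 42), a share under 0.05. Shuffling the shares also broke each gene's straight-line relation to dose share. These splits therefore test for any relation to share and cannot exclude chance for the curvature itself. For cycloheximide with myriocin 2 splits were as large (11 against 47) and for LiCl with myriocin 3 (164 against 384). These shares also lie under 0.05, without adjustment over the pairs. Some shuffled shares called more genes there than the real ones, so chance is not excluded there on this ground either. It is not excluded for LiCl with rapamycin, where 5 splits gave 5 genes or more and 1 gave 578. Splits that call several times the real count point to a structure of the samples, and what it follows was not examined.

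Single cultures stood apart in 5 of 61 sets of gene and group that hold 4 to 10 cultures, in 3 replicates, where chance gives about 1 in 20. In cycloheximide YIL100C-A was lowest in replicate 3 (1.2 against a median of 11.1, gap over range 0.656, estimated depth 104188) and PMR1 was lowest in replicate 1 (gap 0.518, estimated depth 311751). In LiCl replicate 10, the shallowest library with 64843 reads, YOL150C was lowest (3.1 against 51.4, gap 0.767), LCB2 was lowest (24.6 against 54.9, gap 0.527) and GAP1 was highest (against a median of 9.5, gap 0.522).

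The trend with growth inhibition differed between the growth-reference sets, by an interaction term in limma, in 1 gene for cycloheximide, 5 for LiCl, 22 for myriocin and 13 for rapamycin. The sets also differed in density: drug-free cultures ended at an OD600 of 0.553 to 0.7805 in the lower set and 1.377 to 1.4365 in the higher. A slope difference between sets therefore cannot be told apart from one of density. For cycloheximide the gene was GLN1 (slope change 0.79 ± 0.127 in the higher set). For LiCl the genes were FES1 (-1.64 ± 0.275), BTN2 (-2.28 ± 0.443), CHA1 (2.33 ± 0.380), FIT3 (2.33 ± 0.494) and SAM3 (1.63 ± 0.283). Among the 22 for myriocin were ribosome assembly genes with smaller slopes in the higher set, such as DRS1 (-2.59 ± 0.516) and RRP5 (-2.41 ± 0.498). Set and growth range are confounded there: the lower set holds all 5 cultures below a relative growth of 0.35, and the higher set has 6 cultures from 0.41 to 0.931. In cultures of at least 0.35 limma called 0 genes for myriocin, with 422 at an unadjusted p under 0.05 (DRS1 -2.25 ± 0.603, adjusted p = 0.311), a test added after the result was seen. Among the 13 for rapamycin were the chaperone genes SSA4 (-1.34 ± 0.247) and BTN2 (-2.25 ± 0.402). The examples were chosen after their values were seen.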

How the results depend on the processing

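The pseudocount of 10, the library weights, the single libraries left out, the dose share window, the fits within an experiment, the curve over combination cultures, the gradient limited by growth and the removal of repeat features were chosen after seeing the data. Alternatives that need raw counts (other size factors and count models) were not run, since the table holds none. No paired analysis was run: replicate numbers were given in label order and pair nothing, and wells of equal dose in the 2 growth-reference sets were not paired. The balance of higher and lower calls turned in 19 of 117 pairs of count and setting: against no drug in 1 of 9 settings for cycloheximide, 2 for LiCl, 4 for myriocin and 1 for rapamycin, in the trends in 4, 1, 4 and 1 of 8, and in 1 of 11 for LiCl with myriocin. Among these were cycloheximide, LiCl and rapamycin against no drug with no fold minimum (103 higher and 143 lower, 421 and 481, 261 and 325), the cycloheximide trend below an OD600 of 0.9 (103 and 67) and the myriocin trend with a pseudocount of 10 (226 and 163). Position along dose share stayed past the threshold in all 6 pairs over all tested genes and without shallow libraries (r 0.868 to 0.992), but in LiCl with myriocin the median position moved from 0.61 to 0.79 over all tested genes, from below to above the median share of 0.721, and removal of repeat and unmatched features left all 18 counts within 1.5 times. Depth limits low genes most, and 8 libraries lay under 142211 reads. Counts for genes apart from other drugs moved for at least 1 drug in most settings. The growth window and the batch term were among these, so depth is not shown to be the cause. Except where stated, the cause was not tested.

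With no filter rapamycin had 13 genes apart and 481 with a trend. With no fold minimum, which admits small changes by construction, the counts against no drug were 246 (cycloheximide), 902 (LiCl), 735 (myriocin) and 586 (rapamycin), those apart 74 (LiCl) and 20 (myriocin), and the trends 758, 634, 2186 and 1404. Without shallow libraries 4 genes were apart for myriocin and 55 for rapamycin, and 39 for LiCl with 17 of the 36 shared. With the library-number series as batch term myriocin against no drug had 240, the genes apart were 7 (cycloheximide), 20 (myriocin) and 89 (rapamycin), and the pairs 10 (cycloheximide with LiCl) and 164 (cycloheximide with myriocin, 1 of the 10 shared). With growth of 0.40 to 0.60, 7 genes were apart for myriocin and 5 for rapamycin, and with growth as a covariate 3 for rapamycin. Drug-free cultures below an OD600 of 0.9 gave 73 genes for cycloheximide (56 higher, 17 lower, against 73 and 51), and its trend below that OD had 170. A pseudocount of 10, which shrinks changes of low genes, gave 244 (LiCl), 202 (myriocin) and 173 (rapamycin) against no drug, 1 (cycloheximide) and 22 (LiCl) apart, 2 for cycloheximide with myriocin, and trends of 129 (cycloheximide), 389 (myriocin) and 153 (rapamycin). In gradient cultures with a relative growth of at least 0.35 the myriocin trend had 393 genes. Library weights gave 246 genes for cycloheximide against no drug, 11, 61, 51 and 99 apart for cycloheximide, LiCl, myriocin and rapamycin, 2 for cycloheximide with myriocin and 4 for cycloheximide with rapamycin.

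For the pairs in the order cycloheximide with LiCl, with myriocin and with rapamycin, LiCl with myriocin and with rapamycin, and myriocin with rapamycin, departure from interpolation gave 60, 55, 202, 277, 16 and 67 genes, and the curve over combination cultures 109, 11, 114, 164, 5 and 75. Of the departure calls 0, 6, 13, 2, 1 and 0 had the other sign in that curve, whose cultures are also in the departure fit, so agreement was likely. In simulated data with changes of 1 that curve recovered 70%, 10%, 38%, 32%, 40% and 30%. For LiCl with myriocin a dose share of 0.25 to 0.75 gave 62 and its own experiment 2, and for cycloheximide with myriocin its own experiment gave 0. With an estimated correlation 25 of 255 list results stayed (13 higher, 12 lower).

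Leaving out single libraries gave 87 to 131 genes (cycloheximide), 367 to 489 (LiCl), 289 to 381 (myriocin) and 243 to 317 (rapamycin) against no drug. For genes apart the ranges were 0 to 1, 20 to 49, 1 to 58 and 0 to 30. For the pairs in the order above they were 0 to 3, 4 to 100, 0 to 1, 11 to 14, 0 to 1 and 0 to 0.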

Other observations

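All comparisons in this part were chosen after the data were seen.

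Along the myriocin gradient 5 of 13 iron regulon genes rose and 1 fell, and 5 rose in the 17 of 22 cultures with a relative growth of at least 0.35 (limma camera adjusted p = 0.125 with an estimated correlation over all 22). For 4 other lists fewer genes were called in the 17 cultures. Over all 22 cultures 7 of 19 G1/S genes rose, 5 of 15 autophagy genes fell, 5 of 27 ergosterol synthesis genes rose, and 8 of 38 general stress genes fell while 1 rose (adjusted p = 0.237, 0.214, 0.125 and 0.245 with an estimated correlation). In the 17 cultures 2 G1/S genes rose, 0 autophagy genes fell, 2 ergosterol genes rose, and 3 general stress genes fell while 2 rose. The medians went from 0.33 to 0.19 (G1/S), from -0.32 to -0.19 (autophagy), from 0.34 to 0.28 (ergosterol) and from -0.41 to -0.06 (general stress), so for the first 3 lists the sign and over 50% of the size were kept, and the lost calls do not show that these rest on the slower cultures. Along the rapamycin gradient 6 of 24 cell wall integrity genes rose and 1 fell (adjusted p = 0.061 with an estimated correlation), and along the cycloheximide gradient 6 of 24 fell (adjusted p = 0.101 with an estimated correlation).

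For myriocin, list medians differed in sign between the growth-matched comparison with no drug and the full gradient. The 47 amino acid biosynthesis genes had a median of -0.26 in the first and 0.30 in the second, and the 37 oxidative phosphorylation genes 0.26 and -0.29. In the 17 of 22 gradient cultures with a relative growth of at least 0.35 these medians were 0.02 and 0.11, and the phosphate starvation median was -0.33 against -0.01 over all 22 and -0.75 in the growth-matched comparison. The gradient reached a relative growth of 0.0358, below the range of the growth-matched cultures. No test of the difference in sign was run.

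Slopes on growth inhibition were compared across genes, which are not independent replicates. Pearson's r over 5015 genes was 0.059 for LiCl and myriocin, 0.28 for cycloheximide and LiCl, 0.207 for cycloheximide and myriocin, 0.188 for cycloheximide and rapamycin, 0.236 for LiCl and rapamycin and 0.21 for myriocin and rapamycin. Each drug's gradient came from its own experiment with its own drug-free cultures. Genes called for LiCl and myriocin shared their sign in 48 cases and differed in 28, where independent lists would share 27.1, and for myriocin and rapamycin in 74 and 15, where independent lists would share 24.2. In cultures with a relative growth of at least 0.35, a test added after these values were seen, r with the myriocin slopes was 0.13 for cycloheximide, 0.041 for LiCl and 0.179 for rapamycin, and LiCl and myriocin shared 35 signs and differed in 19 (independent lists 13.6), and myriocin and rapamycin 59 and 9 (11.7).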
